A study of Drosophila melanogaster with 2 samples.

How the data were processed

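The samples were 2 biological replicates, numbered 3 and 4, of embryos aged 0 to 12 hours carrying E(spl)m5-HLH with a C-terminal GFP, with chromatin sheared by sonication to 200 to 800 bp, per the labels. Their free-text descriptions call them input controls, in conflict with the assay title and antibody label, and this was not resolved here. Per the deposited text files that accompany the lists, candidate peaks were called on each replicate and on the pooled reads against 1 shared control alignment, and the thresholded list was derived by an irreproducible discovery rate procedure from all 3 candidate lists, on dm6. The aligner, the peak caller, the threshold and the read depth are not given in the sources used here, so no interval for depth could be set. No list from an untagged line or mock precipitation was used here.

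The deposited signal of each peak is the authors' value relative to the control; it was used to rank, filter and describe peaks within a list, and no mean was taken across the separately normalised lists. The deposited −log10 q values were at their maximum in all 2487 thresholded peaks and could not rank them. The thresholded list equalled the 2487 pooled candidates with the highest signal. Each candidate list held 30000 peaks, most of 1 fixed width (29548 of 410 bp in replicate 3, 29570 of 344 bp in replicate 4, and 29285 of 380 bp in the pool), so positions were compared by summit. Coordinates are on dm6 and are given 1-based; the annotation was Ensembl release 115 of the same assembly, and every peak end lay within the chromosome lengths of the reference sequence.

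A gene was called bound when a thresholded summit lay within 1 kb of any of its start sites. The 20 gene lists and 21 motifs were fixed before the data were examined. Of the symbols, 5 older ones were updated and 3 were not matched, 2 in the Bearded family list and 1 in the broadly expressed list. Lists were tested with two-sided Fisher's exact tests and with 10000 random lists matched on start sites and span, whose smallest raw p is 0.0002. Location and replicate overlap were tested with 1000 circular shifts within chromosomes, and annotation shares with 200. Motifs and hexamers were tested with exact McNemar tests between windows of 201 bp on the summit and windows centred 500 bp to 1 side, drawn by a fixed seed. That a subset of peaks keeps the flank side of each peak was set after the values had been seen; the values for all thresholded peaks were the same under both rules. Benjamini-Hochberg adjustment was used within each family, at a threshold of 0.05, and intervals for shares are Wilson intervals that cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

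The named genes are those of the complex, the gene nearest to each of the 20 strongest peaks, and up to 3 members of each other list with the strongest summits; of hexamers, the 5 highest and 5 lowest ratios past the threshold are named. The tests were checked on simulated data over the same number of summits and the same genes: randomly shifted summits gave 0 motifs, 0 hexamers and 0 lists past the threshold. The shift did not keep summits near start sites, so this check did not cover sequence differences between promoters and their flanks. CACGTG planted in 200 centres raised its count by 196 (exact adjusted p = 2.26e-34), and 5 hexamers then passed the threshold, CACGTG among them. Summits planted within 1 kb of the 8 Hox genes were found at all 8, as the planting fixed, and the list passed (exact adjusted p = 9.62e-11). Alternatives were a stricter list, each replicate alone, other distances, matching rules, windows, flanks and backgrounds, and the removal of peaks within 100 kb of E(spl)m5-HLH. Merging summits within 500 bp was added after the data had been seen. With 2 samples in 1 group, no test between groups of samples was possible.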

Results

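Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 0 to 12 hours, of both sexes pooled, from a line carrying E(spl)m5-HLH fused to GFP at its C terminus. E(spl)m5-HLH is a basic helix-loop-helix (bHLH) repressor encoded in the Enhancer of split complex, a cluster of Notch target genes that limit neural fate. The 2 samples form 1 group, with the replicates numbered 3 and 4 in the labels, so the design implies a comparison of the replicates and a description of the bound sites, not a contrast between conditions. The free-text description of both samples calls them input controls, whereas their assay title, sample title and antibody label describe an immunoprecipitation; the values below are given on the second reading. The authors' lists held 30000 candidate peaks for each replicate, 30000 for the pooled reads and 2487 peaks past their reproducibility threshold, called thresholded peaks here. Read depth is unknown from these lists, and signal is the authors' value per peak, on a scale that is not given in the sources used here.

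The replicates placed their strongest peaks at many of the same positions. The strongest peak in both, at rank 1 in each list, lay 47 bp upstream of E(spl)m7-HLH, a bHLH repressor gene of the complex, with a signal of 1048 in replicate 3 and 1253 in replicate 4. The peak upstream of E(spl)m8-HLH, another repressor gene of the complex, ranked 2 in replicate 3 and 6 in replicate 4, and that upstream of the tagged gene, E(spl)m5-HLH, ranked 4 and 7. Peaks further down the list differed more: the summit at tin, which encodes a homeodomain protein needed for heart formation, ranked 340 in replicate 3 and 3781 in replicate 4. Of the 2487 strongest candidates of replicate 3, 57.1% had a summit within 100 bp of one of the 2487 strongest of replicate 4, against a mean of 0.381% and a maximum of 0.844% in 1000 circular shifts (one-sided permutation p = 0.000999, the smallest that these shifts can give). The share was 69.0% for the 100 strongest and 62.2% for the 1000 strongest.

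Of the thresholded peaks, 1443 (58.0%) were among the 2487 strongest of both replicates, and 100 (4.02%) among those of neither. A candidate summit of any strength lay within 100 bp in both replicates for 2302 of them. Across those 2302 peaks the signals had a Spearman rho of 0.469 (95% interval 0.437 to 0.501) and a Pearson r of 0.573 on the log2 scale. These are correlations across peaks within 1 pair of libraries, and peaks are not independent replicates. The thresholded peaks were also those of highest pooled signal, so these correlations and the shares above are conditional on that selection. Matching summits within 50 bp moved rho to 0.567, and using all pooled candidates moved it to 0.629.

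**Figure D1:**
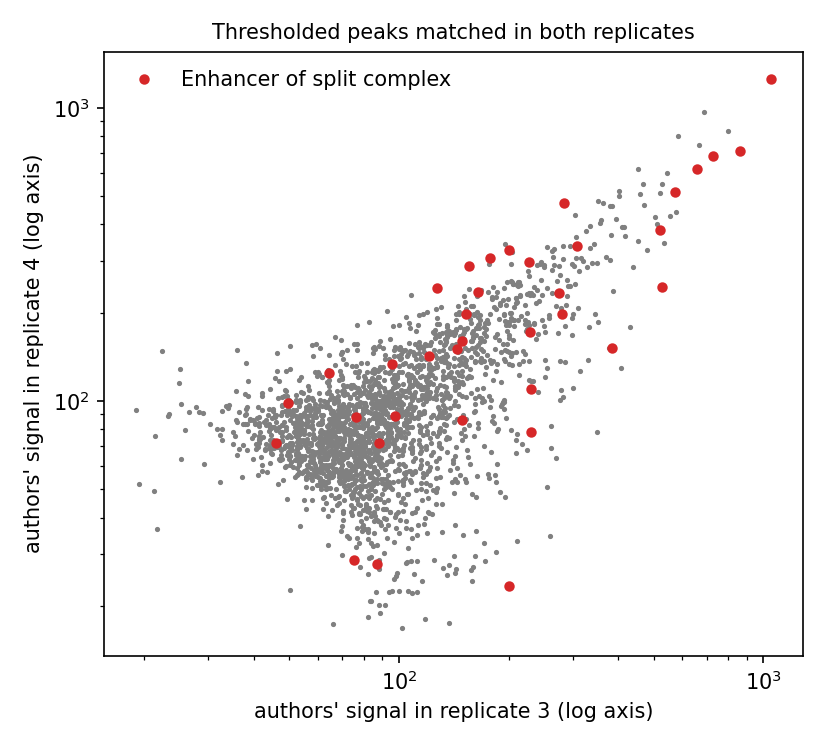
Each point is a thresholded peak matched within 100 bp in both replicates (2302 peaks), with the authors' signal in replicate 3 on the horizontal log axis and in replicate 4 on the vertical log axis; red points lie in the Enhancer of split complex. The peak at E(spl)m7-HLH stands at the upper right, with signals of 1048 and 1253.

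Where the tagged protein was found relative to genes was asked next. Thresholded summits lay close to start sites: 1498 of 2487 (60.2%, 95% Wilson interval 58.3 to 62.1) were within 1 kb of an annotated transcription start site. Shifted positions gave a mean of 23.8% (range 20.6 to 28.3; two-sided permutation p = 0.002, the smallest that these shifts can give). Candidate peaks that did not pass the threshold were near start sites less often, at 39.7% (10934 of 27513; two-sided Fisher's exact p = 2.66e-86). By annotation, 15.7% of summits fell in 5' UTRs against 3.03% of shifted positions, and 1.05% in coding exons against 17.0%. Introns held 42.9% against 42.4%, and intergenic DNA 34.6% against 30.9%. The X chromosome carried 13.2 thresholded peaks per Mb, against 18.4 to 21.2 on the large autosome arms 2L, 2R, 3L and 3R.

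The Enhancer of split complex, at 3R 25997621 to 26049911 (dm6), held the densest group of thresholded summits. With 1 kb added on each side it contained 37 summits, 12 of them among the 100 strongest of the genome, and the densest other window of that extended length held 23. All 7 bHLH repressor genes of the complex had a summit within 1 kb of a start site, as did 5 of the 6 other genes: the Bearded family genes E(spl)malpha-BFM, E(spl)m2-BFM, E(spl)m4-BFM and E(spl)m6-BFM, which encode inhibitors of Neuralized, and gro, which encodes the corepressor recruited by the bHLH proteins. Kaz-m1, a predicted protease inhibitor gene, was the exception, with its nearest summit 1158 bp away. The 12 bound genes of 13 exceeded the rate of other protein-coding genes (two-sided Fisher's exact p = 8.61e-11). That test treats these neighbouring genes as independent.

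The strongest peak of the whole list, with a pooled signal of 2284, had its summit at 3R 26036991, in intergenic DNA 47 bp upstream of E(spl)m7-HLH, and held 1 CACGTG within 100 bp. The peaks 162 bp upstream of E(spl)m8-HLH (signal 1507, rank 4), 935 bp upstream of E(spl)m5-HLH (1404, rank 5) and 99 bp upstream of E(spl)mbeta-HLH (1257, rank 8) came next within the complex. The peak at E(spl)m5-HLH held 1 CACGCG within 100 bp, and those at E(spl)m8-HLH and E(spl)mbeta-HLH held neither CACGTG nor CACGCG. The strongest summits within 1 kb of the other bHLH genes were weaker: E(spl)m3-HLH ranked 36 and E(spl)mgamma-HLH 160, and E(spl)mdelta-HLH had a signal of 490.4. The summit for E(spl)m3-HLH was 843 bp from it and 96 bp from lncRNA:CR43644. That for E(spl)mdelta-HLH was 670 bp from it and 45 bp from CG43116. The summits closest to E(spl)m3-HLH and E(spl)mdelta-HLH, at 109 and 114 bp, ranked 141 and 198. Among the Bearded family genes the ranks were 47 for E(spl)m6-BFM, 91 for E(spl)m4-BFM, 207 for E(spl)malpha-BFM and 356 for E(spl)m2-BFM, and gro stood apart at 1084. The median signal of the 37 summits was 379, which was 2.35 times the median of 161 elsewhere. The tagged gene is normally encoded in this complex; the place, extent and copy number of the tagged insertion are not given in the sources used here.

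**Figure D2:**
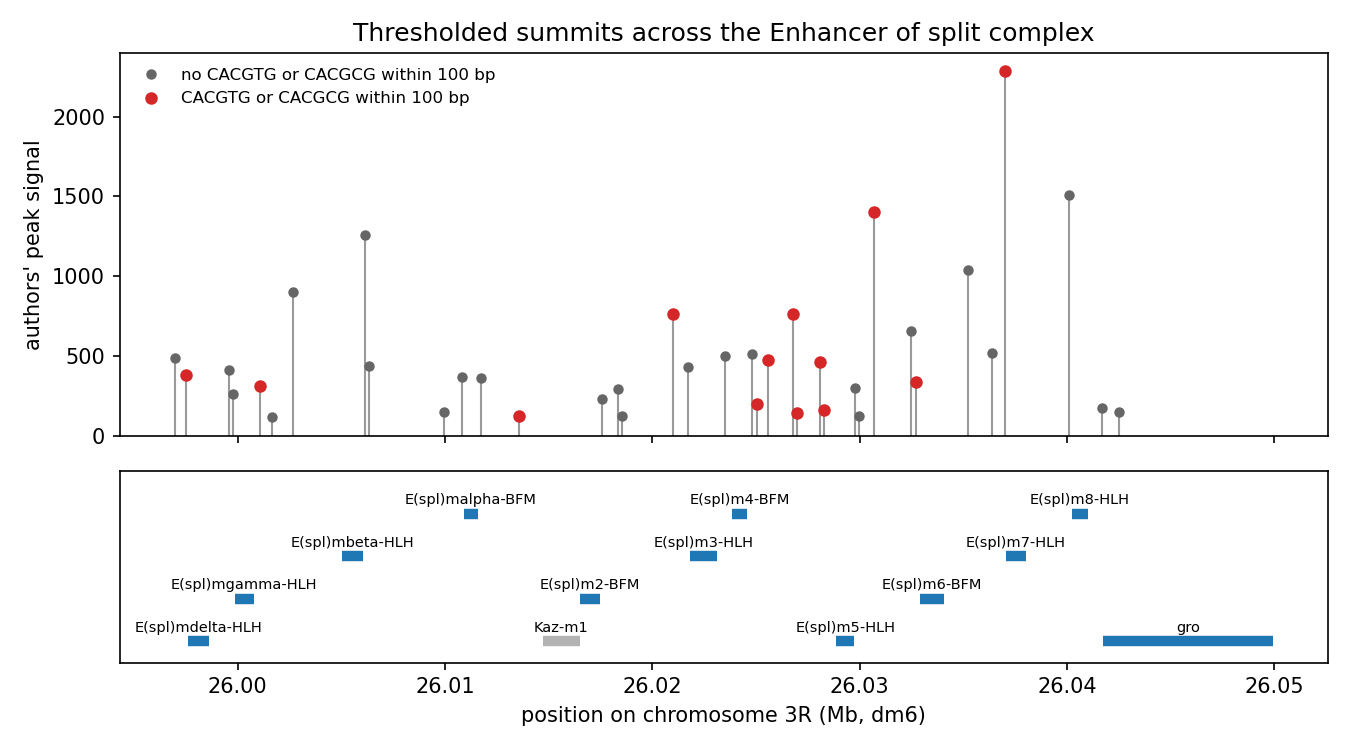
The upper panel gives the authors' signal of each of the 37 thresholded summits (vertical lines, linear axis from 0) by position on 3R in Mb, in red where CACGTG or CACGCG lies within 100 bp; the lower panel gives the 13 genes of the complex, blue where bound and grey for Kaz-m1. The tallest line, at E(spl)m7-HLH, reaches 2284.

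Outside the complex, the other peaks among the 20 strongest lay near genes of varied function. The summit at rank 2 was in an exon of lncRNA:CR31840, 23 bp from its start site, and that at rank 3 was 90 bp upstream of CG14100. Others lay in an intron of sbb (rank 6), 32 bp upstream of Ugalt, a UDP-galactose transporter gene (rank 7), in an intron of cno, whose product links adherens junctions to actin (rank 9), and near px (rank 10) and ph-p, a Polycomb group gene (rank 11). CG1888, CG11050, lncRNA:CR44761, Art3, CG42807, CG9663, lncRNA:CR43951 and Tlk made up the rest, with pooled signals between 915 and 1056. None of these peaks outside the complex held CACGTG or CACGCG within 100 bp. All of the 20 strongest peaks ranked among the 31 strongest of both replicates.

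In all, 1653 of 13945 protein-coding genes (11.9%) had a thresholded summit within 1 kb of a start site, and 20 gene lists fixed before the data were examined were compared with that rate. Genes of early neurogenesis were bound at 11 of 23, among them insc, which orients neuroblast divisions (rank 472), and the Snail family genes wor (605) and esg (759), which act in neuroblasts. Bearded family genes outside the complex were bound at 3 of 4, with 2 other listed symbols unmatched and untested. The bound genes were Brd (416), Ocho (541) and Tom (1001). Ocho had no candidate of replicate 4 within 100 bp, and Tom ranked 2546 in replicate 3. The summits of the 3 bound genes lay side by side, from 3L 14969375 to 14975180, whereas the test treats genes as independent. Notch pathway genes were bound at 7 of 19, including aph-1, a gamma-secretase component (851), neur, the ubiquitin ligase acting on Delta (992), and dx (1033), and Delta and Su(H) were not among them. The summit at aph-1 ranked 2919 in replicate 4. The adjusted p-values were 0.000109, 0.0152 and 0.0128 (two-sided Fisher's exact tests, Benjamini-Hochberg over the 20 lists). The Bearded family list lost the call without replicate 4 (2 of the 4 genes bound; exact adjusted p = 0.152) and with start sites within 5 kb (exact adjusted p = 0.103). The Notch pathway list lost it against random lists matched on start sites and gene span (permutation adjusted p = 0.135), among the 1243 strongest peaks (exact adjusted p = 0.0534) and at 5 kb (exact adjusted p = 0.0725).

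Of 85 ribosomal protein genes, 64 (75.3%, Wilson interval 65.2 to 83.2) had a summit (exact adjusted p = 1.26e-40), where matched lists averaged 12.7 bound genes with an SD of 2.94. The strongest were at RpS27 (rank 23), RpL7 (53) and RpL13A (80). Other broadly expressed genes were bound at 8 of 15 (exact adjusted p = 0.00042), including the chaperone gene Hsp83 (26), the glycolytic gene Gapdh2 (104) and the tubulin gene alphaTub84B (411). None of 119 odorant and gustatory receptor genes was bound (Wilson interval up to 3.13%; exact adjusted p = 3.18e-06).

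The proneural list holds activators of neural fate and other helix-loop-helix genes, among them emc, which is not an activator. It had 4 of 10 genes bound, with emc at rank 489, ato at 540 and ac at 678. The list missed the threshold (exact adjusted p = 0.0509). It passed against matched lists (permutation adjusted p = 0.02), among the 1243 strongest peaks (exact adjusted p = 0.00501) and with start sites within 500 bp (0.0283). Segment polarity genes had 4 of 12 bound (exact adjusted p = 0.0891), with ptc at 469, nkd at 868 and ci at 1068. The dorsoventral list had 5 of 22 bound, with tin at 772, sna at 988 and pnr at 1821, and the gap and pair-rule list 3 of 19, with hry at 553, Kr at 1195 and slp1 at 2469. The other Hairy-related genes had 2 of 6 bound, hry and cwo (1259), and 16.7% without replicate 3, at 500 bp or among the 1243 strongest peaks. Glial genes had 2 of 8, moody (272) and pnt (563), hemocyte genes 1 of 9, ush (1083), and phototransduction genes 1 of 15, Rh5 (460). Muscle structural genes had 1 of 16, Act57B (2023), and 0% without replicate 4. No gene was bound among 8 Hox genes, 9 yolk and larval serum genes or 14 eggshell genes. Ranks in this paragraph are from the pooled list, and some summits lay outside the 2487 strongest of a replicate. In replicate 3, pnr ranked 4528, slp1 6788 and Act57B 3032. In replicate 4, tin ranked 3781, sna 2570 and cwo 3012. At the main settings, none of the lists in this paragraph differed from other genes past the threshold of the Fisher's exact tests. Lists this small leave wide intervals, up to 32.4% for the Hox genes.

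**Figure D3:**
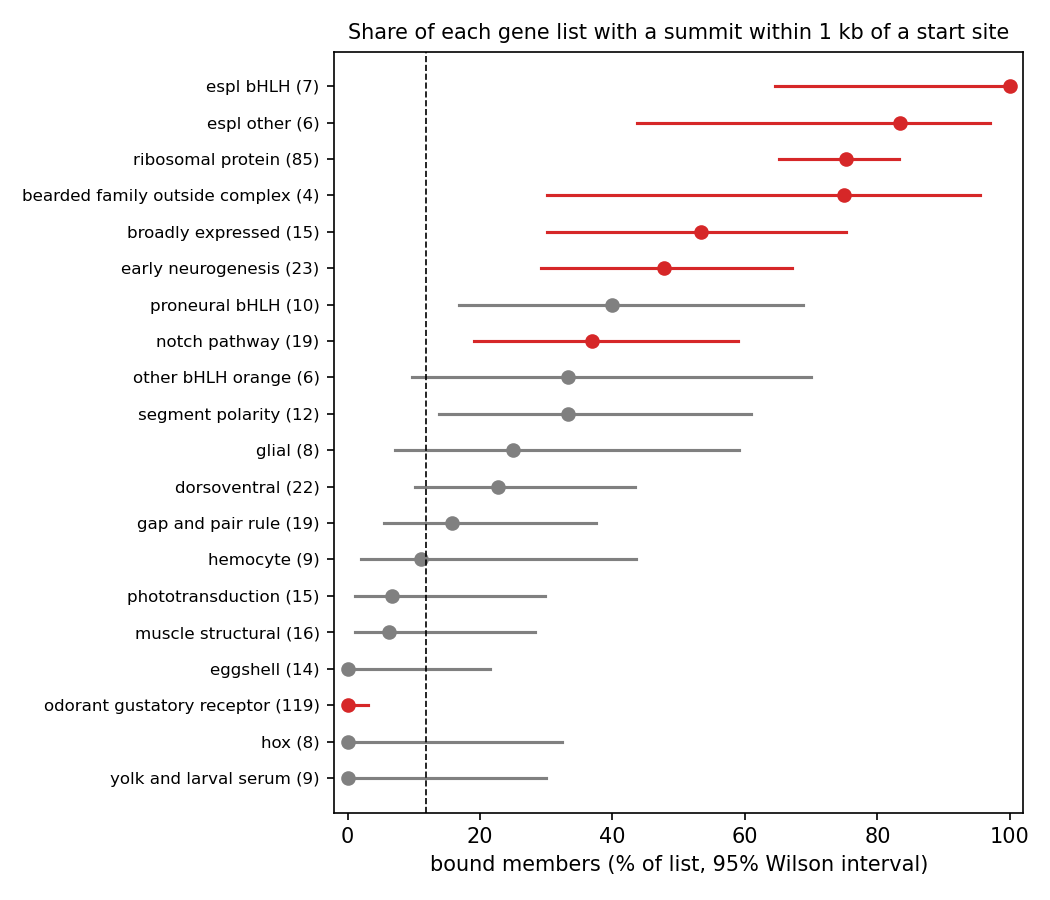
Points give the percentage of each gene list with a thresholded summit within 1 kb of a start site, with 95% Wilson intervals as lines and list sizes in parentheses; red marks lists past the threshold and the dashed line is the 11.9% of all protein-coding genes. Ribosomal protein genes lie at 75.3% and the receptor genes at 0%.

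Sites described for the E(spl) bHLH family were more frequent at summits than beside them. CACGTG occurred within 100 bp of 5.79% of summits (144 of 2487) and in 2.29% of flanking windows centred 500 bp away, a ratio of 2.53 (exact McNemar adjusted p = 1.26e-09 over 21 motifs). CACGCG occurred in 9.81% against 4.83% (adjusted exact p = 3.67e-10), and GGCACGTG in 1.29% against 0.281%. Away from start sites GGCACGTG stood at 1.52% against 0.506%, with no called rise (exact adjusted p = 0.124). The N box, CACNAG, stood at 26.3% against 23.0% (adjusted exact p = 0.0152), but the call was lost without replicate 4 (exact adjusted p = 0.677), among the 1243 strongest peaks (0.439) and near start sites (0.568). The E box bound by proneural proteins, CAGCTG, occurred in 16.2% against 9.45% (adjusted exact p = 7.40e-12). The Su(H) site YGTGRGAA, which marks direct Notch response elements, was found in 2.49% of summits and 2.33% of flanks, a difference that was not detectable with this number of peaks (adjusted exact p = 0.861).

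Sites of general factors were raised over all summits, but each lost its call in a part of them. CAGGTAG, the site of the early activator Zelda, occurred in 2.57% of summits against 1.13% of flanks; the call was lost near start sites (1.54% against 1.34%; exact adjusted p = 0.881) and within 50 bp of summits (0.126). GAGAGAG occurred in 9.61% against 4.95%, and lost the call away from start sites (exact adjusted p = 0.245). The promoter elements TATCGATA and GGTCACACT occurred in 2.77% against 0.724% and 1.37% against 0.201%. Away from start sites TATCGATA was equal in summits and flanks (0.202%) and GGTCACACT had no called rise (exact adjusted p = 1), nor had it among the 1243 strongest peaks (0.0923). In all, 10 motifs were higher at summits, and 6 when only summits over 1 kb from start sites were used. Of 8 palindromes with the base composition of CACGTG, none was higher past the threshold, and CCATGG was lower (2.41% against 3.70%; exact adjusted p = 0.0195), as was AGGACC, a Tramtrack site (2.13% against 3.34%; exact adjusted p = 0.0195). The call for AGGACC was lost among the 1243 strongest peaks (exact adjusted p = 0.335) and within 50 bp (0.402), and its direction turned away from start sites (3.34% against 2.53%; exact adjusted p = 0.581). The call for CCATGG was lost with either replicate left out (exact adjusted p = 0.257 without replicate 3 and 0.114 without replicate 4), among the 1243 strongest peaks and within 50 bp (0.191 in both) and away from start sites (0.736).

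**Figure D4:**
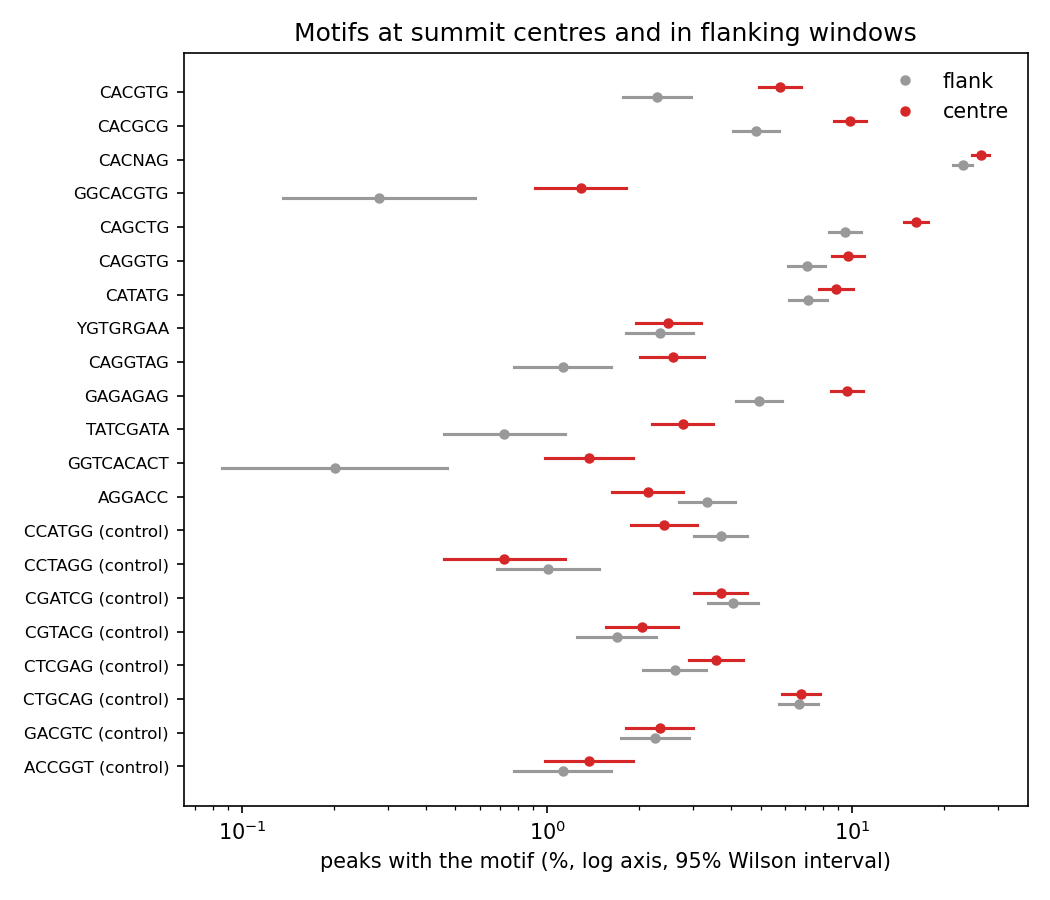
Points give the percentage of 2487 thresholded peaks with each motif at the summit centre (red) or in the flanking window (grey) on a log axis, with 95% Wilson intervals as lines. CACGTG lies at 5.79% in centres and 2.29% in flanks, and the intervals of centre and flank overlap for each of the 8 control palindromes.

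Across all hexamers, tested without regard to known sites, 228 were higher and 254 lower at summits (exact McNemar tests, Benjamini-Hochberg adjusted). CACGTG had the highest ratio of those past the threshold, followed by GCGCGC (2.22), CGCGCG (2.21), CACGCG (2.03) and CGATAG (2.03). The lowest ratios were those of CCAGGA (0.427), AGGACT (0.515), CAAGGA (0.524), ATCTCC (0.525) and GAGGAC (0.526). GC content was 43.3% in centres and 41.9% in flanks. The number of higher hexamers fell to 107 among the 1243 strongest peaks and to 129 in narrower windows reaching 50 bp to each side.

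CACGTG was found in 8.21% of the 621 peaks with the highest signal (51 peaks) and 5.31% of the 621 with the lowest (33 peaks), a difference of 2.90 percentage points that did not pass the threshold (two-sided Fisher's exact p = 0.0542). The difference passed it with the strongest peaks of replicate 4 alone, at 3.38 points (exact p = 0.0226), and of replicate 3 alone, at 3.54 points (exact p = 0.0125). Within the 1243 strongest thresholded peaks it was 6.45 points (exact p = 0.00389). It shrank to 0.965 points when the 1243 strongest were compared with the 1243 weakest (exact p = 0.345), and to 1.77 points within 50 bp of the summit (exact p = 0.144). Over all thresholded peaks in 4 parts, from the highest signal to the lowest, the shares were 8.36, 4.18, 5.31 and 5.31%. They did not fall steadily with signal.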

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

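Tests of the extra copy, of family sites in the complex and of X copy number were chosen after the results they bear on had been seen, as was merging summits as a setting; the rules for reading the tests of strongly transcribed classes and of X copy number were made stricter after their values were seen, which left both open, and the rule for the extra copy was changed more than once after its values were seen, finally by separating 1 extra copy from a larger gain. The matched lists were planned, but were set against gene length as an explanation only after their values were seen, and they do not match gene density.

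Candidate peaks that did not pass the authors' threshold, used above only for their positions, carried CACGTG at 3.27% of centres, CACGCG at 5.80% and CAGCTG at 11.0%, each above their flanks, and were flagged as a signal in data that no comparison of sites had used. The ratio of centre to flank was 1.37 for CACGTG, 1.40 for CACGCG and 1.28 for CAGCTG over 27513 peaks. It was from 1.00 to 1.11 for 7 of 8 control palindromes and 1.25 for GACGTC, with 2 of the 8 past the threshold. Among sites of general factors it was 3.40 for GGTCACACT, 2.11 for TATCGATA, 1.62 for GAGAGAG and 1.26 for CAGGTAG. The rise was therefore not particular to family sites. In comparisons added after the first values were seen, CACGTG differed from the 8 controls pooled (Fisher's exact p = 4.12e-06) and from each of those 7 (highest p = 0.0102, exact), while no difference from GACGTC was detected (Fisher's exact p = 0.236).

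For the peaks of the Enhancer of split complex, splitting of wide sites into several summits would leave no excess after merging, but 29 summits were left after merging within 500 bp, against 19 in the densest other window. The values argue against 1 extra copy of the locus as the whole cause, if signal is proportional to copies: with signals divided by 2, 27 of the 37 summits still reached the lowest thresholded signal, 11 of the 13 genes were still bound (Fisher's exact p = 3.89e-09) and the strongest peak would rank 5 among those elsewhere. A larger gain, of a size not given in the sources used here, cannot be told apart from binding. The genes passed with signals divided by 6 (5 bound, Fisher's exact p = 0.013) and no longer when divided by 7 (4 bound, Fisher's exact p = 0.0576). When divided by 7, 6 summits still reached the lowest thresholded signal. A lost call among 13 genes does not show that the excess was gone. Family sites were found at 35.1% of summits in the complex and 14.7% elsewhere (Fisher's exact p = 0.00186), which leaves binding at such sites as a hypothesis. The summits were not compared with flanking DNA of the complex, so a locus rich in such sites cannot be told apart from binding at them. Some of these summits share a peak interval, and the genes counted above are neighbours, so neither are independent. No group in the design gives a further biological explanation to test.

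The peaks at ribosomal protein genes were weighed next. If gene span and number of start sites were the cause, matched lists would hold as many bound genes. They averaged 12.7 (SD 2.94) against 64 observed. These lists were not matched on the density of neighbouring genes, so they could not test gene-dense regions as an explanation. Recovery of strongly transcribed promoters whatever protein is tagged stays open. Of 3 other classes chosen as strongly transcribed, 0 were bound above other genes past the threshold. Proteasome genes, with 1 of 48 bound (interval up to 10.9%), lay below the 11.9% of other genes. The interval for translation initiation factors reached 34.5% and that for proton pump genes 37.8%. These classes were grouped by symbol and their transcription in these embryos was not measured, so their shares cannot argue against such recovery. The broadly expressed list was raised, and no mock list was used here. CACGTG or CACGCG lay at 26.5% of ribosomal protein promoter summits and 14.97% of other promoter summits (Fisher's exact p = 0.0155), so family sites may contribute as a hypothesis. The summits were not compared with their own flanks here, so promoters rich in such sites cannot be told apart from binding at them. TATCGATA was also more frequent at ribosomal protein promoter summits, at 25.0% against 3.50% (Fisher's exact p = 1.15e-09), as was GGTCACACT, at 10.3% against 1.75% (Fisher's exact p = 0.000396). GAGAGAG was less frequent, at 0% against 12.1% (Fisher's exact p = 0.000315). For CAGCTG, at 10.3% against 16.6%, no difference was detected (Fisher's exact p = 0.238).

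The lower peak density on X was weighed last. Fewer start sites would leave the rate per start site unchanged, yet X had 50.7 promoter summits per 1000 start sites (Wilson interval 44.2 to 58.0), below the lowest large autosome arm at 61.9. A lower copy number of X in pooled sexes cannot be told apart from fewer sites. X held 12.5% of thresholded peaks and 15.1% of candidates that did not pass (Fisher's exact p = 0.000367). Its share did not fall steadily with signal, at 11.3, 13.8, 12.7 and 12.1% in 4 equal parts from the highest signal to the lowest. Copy number would act on these shares only if signal follows the number of copies, and the scale of the signal is not given in the sources used here. No biological explanation was tested.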

How the results depend on the processing

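Of 381 values under alternatives, 303 kept their direction and side of the threshold or their size. Merging summits within 500 bp, added after seeing the data, left 29 summits in the complex and 8 gene lists past the threshold. Higher hexamers numbered 107 among the 1243 strongest peaks and 129 in windows reaching 50 bp to each side, where fewer peaks or bases were tested, and higher motifs 6 away from start sites. The difference in CACGTG by signal, 2.90 points, passed the threshold at 6.45 among the 1243 strongest and at 3.38 to 3.54 with 1 replicate left out, and shrank to 0.965 between the 1243 strongest and weakest peaks and to 1.77 within 50 bp, not past it. The Spearman correlation of signal between the replicates moved to 0.567 within 50 bp and 0.629 over all candidates. The cause of these last 2 was not tested. Among single motifs, calls were also lost for CAGGTG without replicate 4 (exact adjusted p = 0.0603), among the 1243 strongest (0.201), with flanks 1000 bp away (0.0676) and near start sites (0.568), for CAGGTAG within 50 bp (0.126) and near start sites (0.881), for GAGAGAG (0.245) and GGCACGTG (0.124) away from start sites, for GGTCACACT among the 1243 strongest (0.0923) and away from start sites (1), for AGGACC among the 1243 strongest (0.335) and within 50 bp (0.402), and for CCATGG, beyond either replicate left out, among the 1243 strongest (0.191), within 50 bp (0.191) and away from start sites (0.736). CATATG passed without replicate 3 (exact adjusted p = 0.0103), within 50 bp (0.0109) and with flanks 1000 bp away (0.00446). The proneural list passed among the 1243 strongest (exact adjusted p = 0.00501), at 500 bp (0.0283) and without replicate 3 (0.046), and it and the segment polarity list passed with the nearest start site only (0.0216 and 0.0392).

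The 34 reversals were of direction; apart from both complex lists, which fell to 0% by construction without peaks within 100 kb of E(spl)m5-HLH, and those named next, they concern results that did not pass the threshold, and none passed it when reversed. Past the threshold in the main test, TATCGATA was equal in centre and flank away from start sites (0.202%), and AGGACC was reversed there (3.34%). Bound shares reversed for hemocyte genes at 11.1% (1243 strongest, 500 bp, nearest start site), phototransduction genes at 6.67% (1243 strongest), gap and pair-rule genes at 10.5% (without replicate 4; 26.3% without replicate 3) and 21.1% (5 kb), and, at 5 kb, Hox genes at 25.0% and yolk and serum genes at 33.3%. Centre shares reversed for YGTGRGAA at 2.09% (1243 strongest) and 2.41% (without replicate 4; 2.81% without replicate 3). Control palindromes, which had no called rise, reversed or were equal as follows: among the 1243 strongest CGATCG 4.02% and CTCGAG 2.98%; without replicate 3 CTGCAG 6.88%, GACGTC 2.25% and ACCGGT 1.41%; without replicate 4 CTCGAG 3.02% (3.22% without replicate 3), CTGCAG 6.43%, GACGTC 2.57% and ACCGGT 1.33%; within 50 bp CTGCAG 3.74%, GACGTC 1.01% and ACCGGT 0.442%; with flanks 1000 bp away CGATCG 3.70%, CTGCAG 6.80% and GACGTC 2.33%; away from start sites CGATCG 3.54% and ACCGGT 0.809%; near them CGTACG 2.27%, CTGCAG 6.01% and GACGTC 2.47%. The cause of these was not tested. The number of peaks and genes limits these values; read depth is unknown.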

Other observations

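The tests of Zelda and GAGA sites and the 11 gene classes below, grouped by symbol, were chosen after the data had been seen.

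Classes of genes used outside the early embryo or in detoxification were bound rarely: 0 of 70 Cpr cuticle protein genes (exact adjusted p = 0.00292), 0 of 60 ionotropic receptor genes (exact adjusted p = 0.00516) and 2 of 85 cytochrome P450 genes, Cyp305a1 and Cyp6u1 (exact adjusted p = 0.0129). None of these passed the threshold against matched lists (permutation adjusted p = 0.0506, 0.0506 and 0.094). Mitochondrial ribosomal protein genes had 11 of 73 bound, where cytoplasmic ones had 64 of 85, proteasome genes 1 of 48 (Rpn13), translation initiation factors 9 of 44, proton pump genes 7 of 33, respiratory complex I genes 4 of 40, splicing genes 2 of 20 (Prp3 and SmD3), tRNA synthetases 1 of 18 (GluProRS) and chromatin regulators 3 of 6 (Gcn5, brm and nej), none past the threshold after adjustment.

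Promoter and distal summits differed in their sites. CAGGTAG, the Zelda site, lay at 4.15% of summits over 1 kb from start sites against 0.809% of their flanks, and at 1.54% against 1.34% near start sites; the balance of peaks with it only in the centre or only in the flank differed between them (Fisher's exact p = 0.00264). GAGAGAG went the other way, at 11.5% against 4.94% near start sites and 6.67% against 4.95% away from them (Fisher's exact p = 0.00898). Zelda sites may therefore mark the distal sites more than the promoter ones, as a hypothesis.

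Of the strongest peaks of each replicate, 467 in replicate 3 and 321 in replicate 4 had no candidate of the other within 100 bp, but only 60 and 57 had none within 400 bp. CACGTG or CACGCG lay at 8.99% of those of replicate 3, below 16.5% of its peaks shared with the strongest of replicate 4 (Fisher's exact p = 4.28e-05). In replicate 4 the shares were 14.6% and 16.5%, and no difference was detected (Fisher's exact p = 0.45). The test was made within each replicate after a pooled test had been seen. Of 290 tRNA genes, 5 had a summit within 200 bp of their middle, a share of summits within the range of shifted positions (permutation p = 0.106). The densest window outside the complex, at 2R 13539796 to 13594085, was singled out after its value was seen; it holds link, Roe1, fand, Nadk1a, Nadk1b and CG42807 among others.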
